A study of Mus musculus with 18 samples.

How the data were processed

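RNA sequencing libraries were made from RAW264.7 cells, a mouse macrophage-like line, treated for 6 h in serum-free medium. The 18 libraries fall into 6 groups of 3: DMSO, 20 uM cGAMP, 20 uM SB24011, 20 uM cGAMP with 10 uM SB24011, 20 uM cGAMP with 20 uM SB24011, and 20 uM cGAMP with 20 uM of the analog 7a. RNA was prepared with an RNeasy plus kit and libraries with a TruSeq stranded mRNA kit. The labels do not state whether the 3 replicates of a group were separate cultures, so the p-values of single genes and scores measure only the spread between libraries.

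The authors' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b with the mouse build GRCm38 (mm10). The role of each program, the read counter, the strand setting and the treatment of reads with several positions are not given in the sources used here. The deposited gene table holds, per the file headers, a raw read count and an FPKM value for each of 45777 genes in each library. A second deposited table holds log2(FPKM + 1) values that the authors quantile-normalized over the 18 libraries. It lists the 13908 genes whose read count is above 0 in every library, and its scale was checked against the FPKM columns. The TPM columns were not used here. Genes are named by the symbols and NCBI Gene IDs in the deposited table, and 45679 of the IDs were found in the RefSeq gene table of GRCm38, which gave the coordinates. Tmem173 is the symbol that the deposited table uses for Sting1.

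Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the groups, which left 14650 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with robust dispersions was fitted to the 18 libraries, with 12 residual degrees of freedom. The 8 comparisons were 7 differences between pairs of groups and the interaction of cGAMP with 20 uM SB24011, which is the change with SB24011 on cGAMP minus the change with SB24011 alone on the log2 scale. Each was a two-sided quasi-likelihood F-test. The p-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are edgeR's, with a prior count of 0.125, and SE is the standard error derived from the F statistic. Levels are TMM-scaled CPM (read counts scaled to a common library size), given as the group mean with the SD over 3 libraries.

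Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for named genes were fixed, except where an alternative or test is said to have been chosen later. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists within each comparison. Camera sets the members of a list against the other genes, so its p-value does not measure the spread between libraries alone. The test was repeated with a correlation estimated from the libraries. Beside the members called over all genes, calls adjusted over the list alone were counted. A list score is the mean over its members of log2 CPM with a prior count of 2, compared between groups of 3 by an exact two-sided permutation test, whose smallest possible p is 0.1. The type I interferon list was represented by Ifnb1, its 1 tested member. Some genes stand in 2 lists, such as Sqstm1 and Slc7a11.

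Named genes were chosen by rule. The first part took, for each comparison, the 8 called genes with the largest rise and the 8 with the largest fall among genes with a mean of at least 1 CPM and, for pairs of groups, no overlap between the libraries. The second part took up to 4 called members, by absolute fold change, of each list that passed camera. The third part took Ifnb1, Cxcl10, Ifit1, Isg15, Tnf, Il6, Tmem173 and Trim29 in every comparison. Genes named only by a clone or locus number were mostly left out of the text. The exceptions of 1 list are given as a count, and 1 gene among them is not reported here. Of 147 named genes tested, 34 overlap another tested gene on the map and 10 overlap one with a higher mean CPM, among them Ccne2 and Angptl6.

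A fold against a group with a count of 0 in all 3 libraries was computed against a floor of 3 counts over the group and is written as a lower bound. Such floors cover counting error only, while the 95% intervals of fold changes come from the fitted model. Library totals ranged from 45165780 to 65810517 counts, so that 3 counts in a library correspond to between 0.0456 and 0.0664 CPM before TMM scaling.

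Library numbers in the labels form sets: 1 to 6 (replicate 1 of each group), 21 to 26 (replicate 2) and 31 to 36 (replicate 3). Whether the numbers pair the libraries was checked by correlating each library's deviations from its group mean. Each of 18 libraries correlated best with a library of its own set, with a median r of 0.122 over the 45 same-set pairs and -0.0615 over the others. Every pair exceeded the minimum of 0.1 for SB24011 against DMSO (r from 0.125 to 0.178) and for 7a on cGAMP (0.137 to 0.183). In the other 5 pairwise comparisons at least 1 pair lay below it.

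Alternatives fixed beforehand were RLE size factors, no filter on low counts, the library set as a replicate block, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, limma on the deposited log2 values of genes with a mean of at least 1 FPKM, a threshold of 2-fold, and leaving out each library in turn. Scaling by library size alone and leaving out library set 1, which a principal component separated from the others, were chosen after seeing the data. The pipeline was tested on simulated data with the means, dispersions and library sizes of the 14650 genes, of which 200 were changed by 1.5-fold, 2-fold or 4-fold. For cGAMP against DMSO edgeR recovered 61.2%, 76.1% and 83.3% of these by size of change, with 8 false calls among 14390 unchanged genes. For SB24011 alone it recovered 58.2%, 74.6% and 86.4%, with 6 false calls. For 20 uM SB24011 on cGAMP the shares were 64.2%, 74.6% and 89.4%, with 11 false calls, and for 10 uM they were 59.7%, 68.7% and 92.4%, with 4. For 7a on cGAMP they were 56.7%, 73.1% and 90.9%, with 11 false calls, and for SB24011 against 7a 56.7%, 71.6% and 92.4%, with 6. For the doses they were 56.7%, 77.6% and 87.9%, with 8 false calls, and for the interaction 52.2%, 68.7% and 83.3%, with 5. No recovered gene had the wrong direction. Camera called a list shifted by 1.5-fold in 8 of 8 simulations and another list in 1. The simulated genes were drawn independently and without an effect of the library set. These simulations therefore cannot show how often camera calls a list whose members vary together. They also changed few genes, while edgeR called 5193 genes for cGAMP against DMSO and 6541 for SB24011 alone. Recovery and false calls may differ where so many genes change. In the first simulation DESeq2 recovered 157 of 200 genes with 28 false calls and limma 149 with 8.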

Results

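Gene expression was measured by mRNA sequencing in RAW264.7 cells, a mouse macrophage-like line, after 6 h with cGAMP, SB24011, combinations of these, or DMSO as the vehicle control. cGAMP is a cyclic dinucleotide that activates the adaptor protein STING. The series title calls SB24011 an inhibitor of the interaction between STING and TRIM29, and the design calls 7a its negative analog. Each of the 6 groups had 3 libraries. The total read count averaged 59.8 (in units of 1e+06) in the DMSO libraries, 51.2 with cGAMP, 54.9 with SB24011 alone, 53.2 with cGAMP and 10 uM SB24011, 51.7 with cGAMP and 20 uM SB24011, and 55.9 with cGAMP and 7a. Transcripts of the mitochondrial genome took 2.85% ± 0.170 (SD, n = 3) of the counts in DMSO. With cGAMP they took 2.298% ± 0.145. Ribosomal protein genes took 4.34% ± 0.0275 in DMSO, 3.90% ± 0.0988 with cGAMP and 4.56% ± 0.0676 with SB24011 alone. Mean TMM factors were 1.04 in DMSO, 0.953 with cGAMP and 1.10 with SB24011 alone. The first 2 principal components held 40.3% and 25.1% of the variance between libraries, and the third, with 4.09%, separated replicate 1 of the groups from the others.

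The first comparison, cGAMP against DMSO, asks what activation of STING changed in these cells. The interferon response rose throughout its list. Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522794 in GRCm38), went from 0.0669 ± 0.0580 CPM (SD, n = 3) to 2.08 ± 0.261 CPM, a log2 fold change of 4.97 ± 0.46 (SE). Cxcl10, a chemokine that attracts T cells (chromosome 5, 92346638 to 92348889), rose from 11.8 ± 2.27 to 1126 ± 133 CPM, by 6.58 ± 0.40 on the log2 scale. Each of 60 tested interferon-stimulated genes rose, over all genes and adjusted over the list alone, with a median log2 fold change of 3.02 (camera adjusted p = 7.56e-118, and adjusted p = 0.0147 with an estimated correlation). Large rises in the list were in Iigp1 (7.94 ± 0.62), Gbp5 (7.64 ± 0.64) and Gbp2 (7.19 ± 0.59). The antiviral genes Ifit1 (chromosome 19, 34640889 to 34650009) and Isg15 (chromosome 4, 156199424 to 156200818) rose by 5.32 ± 0.35 and 3.61 ± 0.23. The mean score of this list was 4.86 ± 0.093 (log2 CPM, SD) in DMSO and 8.53 ± 0.152 with cGAMP, higher in 3 of 3 libraries (exact permutation p = 0.1, the smallest possible with 3 against 3).

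Antigen presentation by MHC class I rose too, with 22 of 25 genes up, the same count adjusted over the list alone, and a median of 1.42 (camera adjusted p = 3.1e-35, 0.0147 with an estimated correlation). Among them were the peptide transporter genes Tap1 (3.04 ± 0.21) and Tap2 (2.49 ± 0.22) and their regulator Nlrc5 (2.97 ± 0.18). Of 29 cytokine and chemokine genes 19 rose and none fell, the same over the list alone, with a median of 1.97 (camera adjusted p = 9.82e-13, but adjusted p = 0.209 with an estimated correlation). Tnf rose from 71.9 ± 13.6 to 282 ± 13.5 CPM (1.97 ± 0.16). Il6 had no read in DMSO and was at least 19.4-fold higher with cGAMP, Ccl12 at least 31.9-fold and Cxcl9 at least 108-fold. Of 41 NF-kB feedback and target genes 24 rose and 1 fell (30 and 1 adjusted over the list alone) (camera adjusted p = 1.37e-08, 0.396 with an estimated correlation). The costimulatory receptor gene Cd40 rose by 5.60 ± 0.60 and the nitric oxide synthase gene Nos2 by 4.27 ± 0.34. The 1 that fell was Sod2 (-0.23), named here, like other exceptions to a list below, after its value was seen. Of 38 immediate early and MAPK feedback genes 19 rose and 5 fell (23 and 5 over the list alone) (camera adjusted p = 0.00431, 0.375 with an estimated correlation). Dusp2 rose by 2.17 ± 0.31 and Zfp36 by 1.68 ± 0.22.

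**Figure D1:**
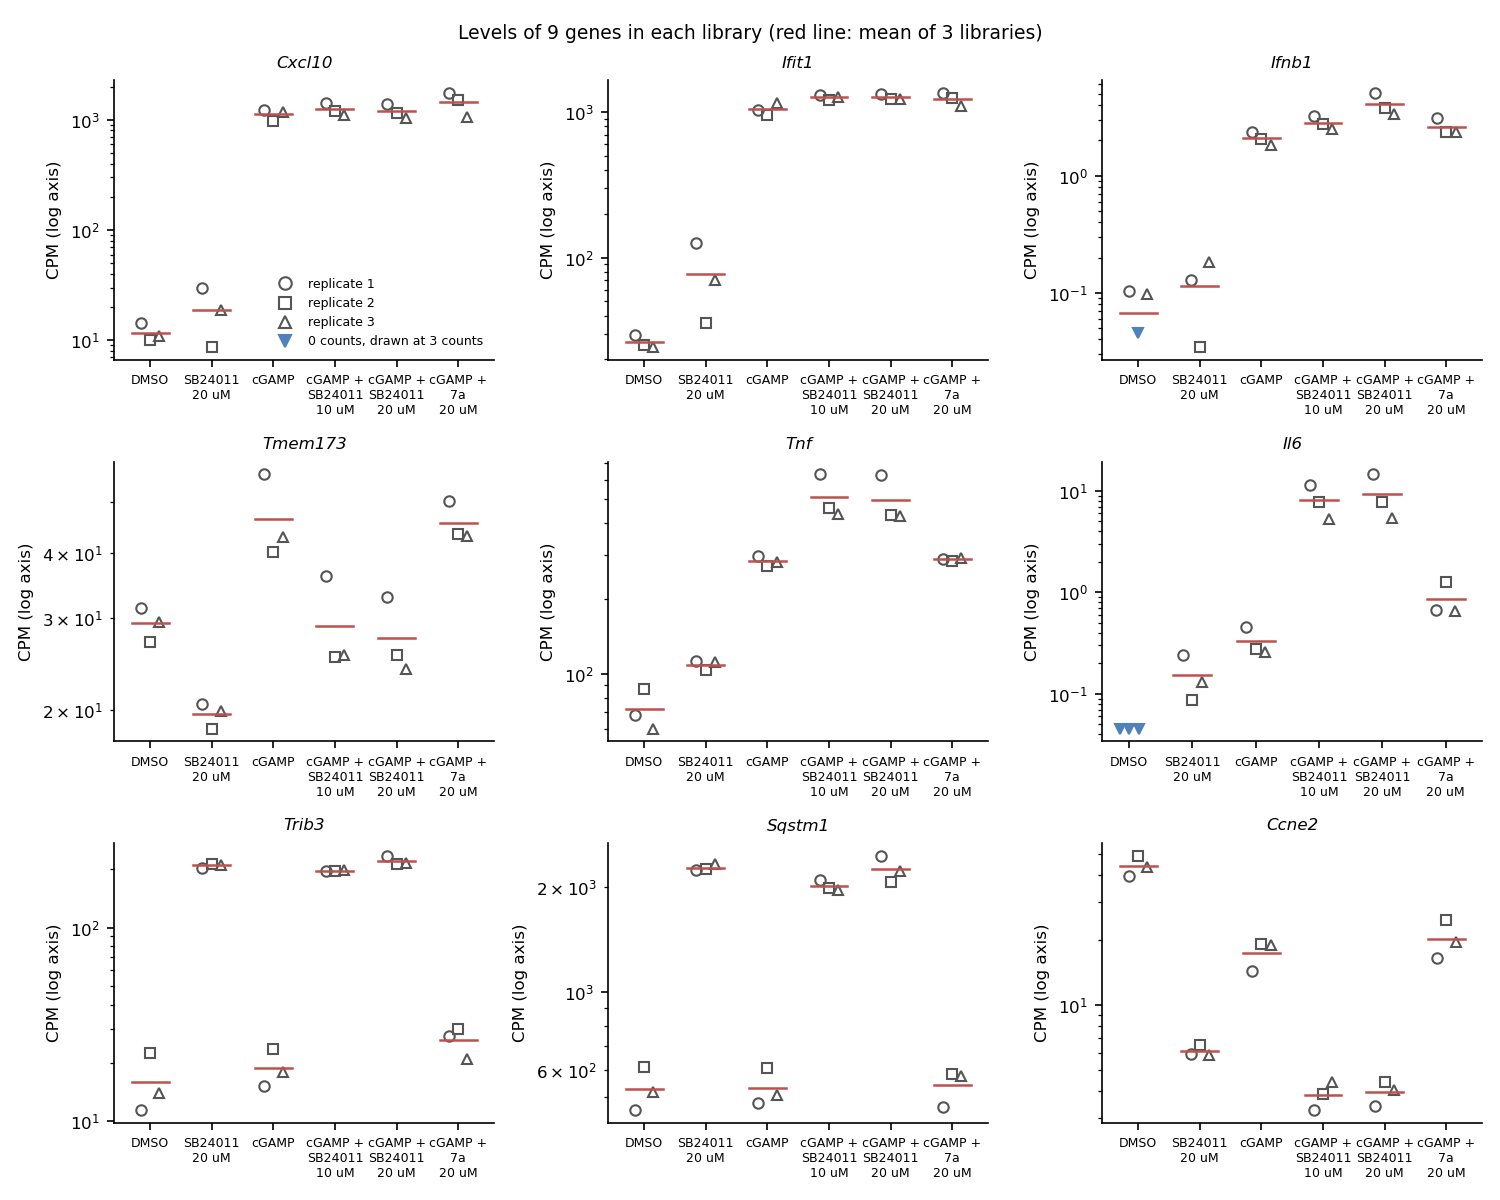
Level in CPM (log axis) of Cxcl10, Ifit1, Ifnb1, Tmem173, Tnf, Il6, Trib3, Sqstm1 and Ccne2 in each of the 18 libraries, with the mean of 3 as a red line and libraries without a read drawn at the floor of 3 counts. Cxcl10 and Ifit1 are high in the 4 groups with cGAMP, Trib3 and Sqstm1 are highest in the 3 groups with SB24011, and Il6 in the 2 groups with SB24011 on cGAMP.

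Components of the cGAS-STING pathway moved both ways, with 19 of 41 up and 10 down (19 and 11 over the list alone). The median was 0.09 (0.136 without cGAMP replicate 3), with a camera adjusted p of 0.000391 upward (0.209 with an estimated correlation). The members with the largest rise were themselves interferon-inducible, such as the DNA sensors Ifi209 (6.66 ± 0.32) and Ifi204 (4.69 ± 0.23), the DNase gene Trex1 (2.49 ± 0.34) and the transcription factor gene Irf7 (2.27 ± 0.16). Tmem173, which encodes STING (chromosome 18, 35733678 to 35740554), rose from 29.4 ± 2.21 to 46.5 ± 8.81 CPM (0.67 ± 0.15, adjusted p = 0.00244). Trim29 (chromosome 9, 43310715 to 43336125) was not detectable at this depth in 17 of 18 libraries and had 5 reads in cGAMP replicate 2, so no comparison gave it a test. The heat shock genes Hspa1b (2.19 ± 0.33) and Hspa1a (2.16 ± 0.30) rose. In their list 12 of 26 rose and none fell (14 over the list alone, camera adjusted p = 0.00319, 0.361 with an estimated correlation).

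Genes of growth and of cholesterol synthesis fell with cGAMP. Of 45 DNA replication genes 35 fell and 2 rose (36 and 3 over the list alone), with a median of -0.45 (camera adjusted p = 1.98e-12, 0.147 with an estimated correlation). Ccne2, a cyclin of S phase entry (chromosome 4, 11190433 to 11204779, a span shared with Ints8), fell by 1.34 ± 0.14, E2f7 by 1.22 ± 0.11 and Tk1 by 1.12 ± 0.14, while Mcm10 and Rfc3 rose. Of 40 mitotic genes 23 fell and 1, Cenpe, rose (26 and 1 over the list alone), with Incenp at -0.58 ± 0.07 (camera adjusted p = 0.000158, 0.619 with an estimated correlation). Of 25 cholesterol biosynthesis genes 19 fell and 2 rose (20 and 2 over the list alone) (camera adjusted p = 1.17e-05, 0.209 with an estimated correlation). Dhcr7 fell by 0.70 ± 0.07 and Mvd by 0.69 ± 0.06. Cx3cr1, the receptor of fractalkine and a member of the macrophage identity list, fell from 100.4 ± 18.3 to 21.5 ± 0.951 CPM (-2.22 ± 0.22). Outside the lists, S1pr1 fell by 2.25 ± 0.48 and Angptl4 by 2.07 ± 0.38. Several transcripts with no read in the DMSO libraries appeared, with Pax5 at least 134-fold higher, Kalrn at least 129-fold and the killer cell receptor gene Klrk1 at least 99.6-fold.

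Over all 14650 genes edgeR called 5193 for cGAMP against DMSO, 2290 up and 2903 down, of which 841 and 260 changed at least 2-fold. The libraries of the groups did not overlap in 47.6% of genes, where chance gives 10%. The split between up and down depends on scaling. Scaling by library size alone moved the median log2 fold change of all genes from -0.0571 to -0.184. It moved the share of called genes that rose from 44.1% to 24.9%, and limma on log2 FPKM gave 32.7%.

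**Figure D2:**
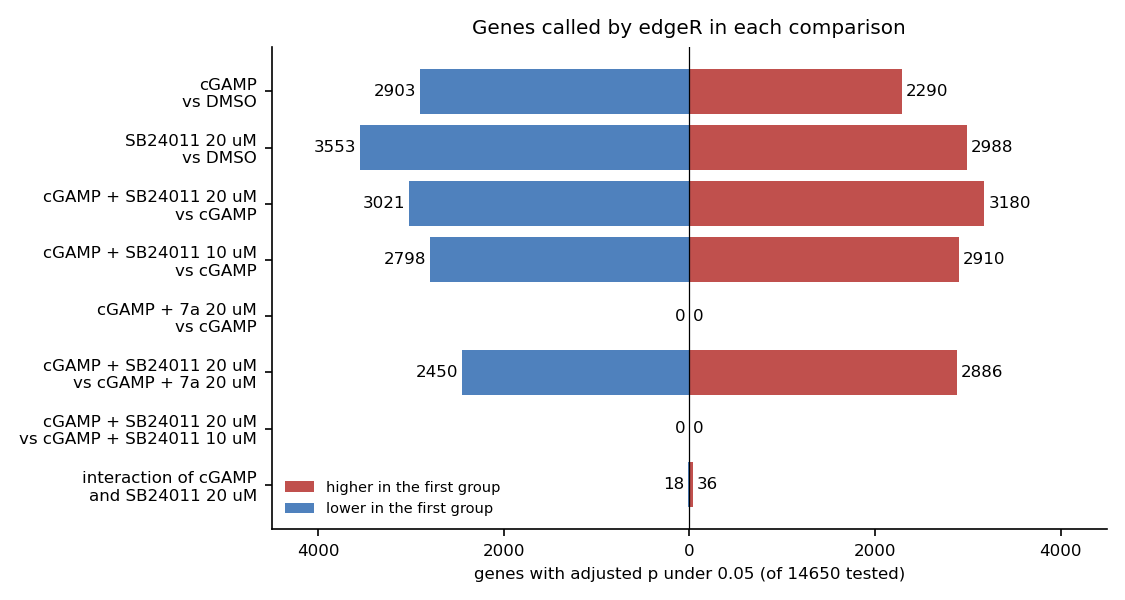
Number of genes called by edgeR at an adjusted p under 0.05 in each of the 8 comparisons, with genes that rose and fell as separate bars. The bars for 7a on cGAMP and for the doses are at 0.

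SB24011 alone against DMSO asks what the compound changed without cGAMP. Targets of the stress transcription factor ATF4 rose nearly throughout. The pseudokinase gene Trib3 (chromosome 2, 152337425 to 152344060) went from 16 ± 5.73 to 209 ± 4.39 CPM (SD, n = 3), a log2 fold change of 3.71 ± 0.22 (SE). Gdf15, a stress cytokine, rose by 3.48 ± 0.28 and Cth, an enzyme of cysteine synthesis, by 3.39 ± 0.13. Of 38 genes of the integrated stress response list 36 rose and none fell, the same over the list alone, with a median of 1.26 (camera adjusted p = 2.72e-65, 0.000973 with an estimated correlation). The other 2, Psat1 and Slc1a5, were not called (0.10 and -0.05). The autophagy receptor gene Sqstm1 (chromosome 11, 50200152 to 50210820) rose from 530 ± 75.9 to 2274 ± 45.3 CPM (2.101 ± 0.11). Of 42 lysosome and autophagy genes 20 rose and 6 fell, the same over the list alone (camera adjusted p = 0.00214, 0.243 with an estimated correlation). Npc1, a cholesterol exporter of lysosomes, rose by 1.08 ± 0.06 and the lysosomal channel gene Mcoln1 by 0.62 ± 0.06.

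DNA replication genes fell with SB24011 in 45 of 45 cases, over all genes and over the list alone, with a median of -1.02 (camera adjusted p = 3.95e-56, 0.00142 with an estimated correlation). Ccne2 fell by 2.85 ± 0.15, Ccne1 by 2.42 ± 0.15, the origin licensing gene Cdc6 (chromosome 11, 98907709 to 98923942) by 2.31 ± 0.12 and E2f7 by 2.03 ± 0.12. Ung, a DNA repair glycosylase outside the list, fell by 2.81 ± 0.27. Of 40 mitotic genes 34 fell and none rose (36 over the list alone), with Aurkb at -0.89 ± 0.11 (camera adjusted p = 2.01e-08, 0.757 with an estimated correlation). The heat shock genes Hspa1b and Hspa1a (chromosome 17, 34969359 to 34972156) fell by 3.11 ± 0.41 and 2.94 ± 0.38, and Hspa8 fell by 1.26 ± 0.11. In their list 20 of 26 fell and 2, Dnajb4 and Ubb, rose (22 and 2 over the list alone, camera adjusted p = 1.96e-05, 0.244 with an estimated correlation). Of 25 cholesterol biosynthesis genes 21 fell and none rose, the same over the list alone, with Acat2 at -1.19 ± 0.07 and Hmgcs1 at -0.90 ± 0.06 (camera adjusted p = 1.33e-09, 0.0911 with an estimated correlation). Of 36 ribosome biogenesis genes 25 fell and 3 rose (26 and 3 over the list alone) (camera adjusted p = 0.000666, 0.929 with an estimated correlation). Polr1b fell by 0.70 ± 0.09, while the transcription factor gene Myc rose by 2.55 ± 0.30.

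Interferon-stimulated genes rose modestly with SB24011 alone. Of 60, 36 rose and 1, Eif2ak2, fell (39 and 1 over the list alone), with a median of 0.68 (camera adjusted p = 6.54e-06, but adjusted p = 0.929 with an estimated correlation). Without SB24011 replicate 1 the median was 0.33. Ifit3 rose by 1.72 ± 0.32 and Isg15 by 0.92 ± 0.21 (0.606 without that replicate). Ifit1 rose from 26.3 ± 2.72 to 77.4 ± 45.9 CPM (1.56 ± 0.30, adjusted p = 0.000687) and Rsad2 by 1.68 ± 0.35. Without SB24011 replicate 1 these 2 rose by 1.004 and 1.07, and the calls ended when only the 2 groups were fitted (adjusted p = 0.0516 and 0.054). The list score rose from 4.86 ± 0.093 to 5.53 ± 0.470 (log2 CPM), higher in 3 of 3 libraries (exact permutation p = 0.1). The difference of 0.664 was 0.411 without SB24011 replicate 1. Ifnb1 stood at 0.115 ± 0.0747 CPM and was not called (0.82 ± 0.64, adjusted p = 0.318), and Cxcl10 was not called at 19 ± 10.5 CPM (0.69 ± 0.33, adjusted p = 0.103) except without SB24011 replicate 2 (1.04, adjusted p = 0.00321). Tmem173 fell by 0.58 ± 0.15 (adjusted p = 0.00543). Tnf rose by 0.60 ± 0.16 (adjusted p = 0.00613), Cxcl2 by 3.00 ± 0.42 and Csf1 by 2.37 ± 0.30, and Il6 was at least 10.2-fold higher than in DMSO, where it had no read.

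As lists, cytokines and chemokines (9 of 29 up, none down, the same over the list alone) and NF-kB genes (15 of 41 up, 4 down, the same over the list alone) lay close to the threshold with SB24011 alone. The cytokine list had a camera adjusted p of 0.0339 (0.929 with an estimated correlation). It lost its call without DMSO replicate 3 (0.0728) or SB24011 replicate 1 (0.0822), with RLE size factors (0.0518), with library size alone (0.0822) and without library set 1 (0.0647). The NF-kB list had 0.0435 (0.929 with an estimated correlation). Its adjusted p was 0.0507 without DMSO replicate 2, 0.0713 without DMSO replicate 3, 0.149 without SB24011 replicate 1, 0.0569 with RLE and 0.0725 with library size alone. The NRF2 list of oxidative stress genes, with 12 of 37 up and 5 down, the same over the list alone, did not pass (0.128). It passed with the library set as a replicate block (0.0324) and without DMSO replicate 2 (0.0153). Genes with a large rise outside the lists were Car6, a secreted carbonic anhydrase (7.31 ± 0.56), Extl1 (4.98 ± 0.28), Fbln5 (4.47 ± 0.72) and the aquaporin gene Aqp9 (4.38 ± 0.29). Cx3cr1 fell by 2.49 ± 0.22 and Arc by 2.72 ± 0.26. Over all genes edgeR called 6541, with 2988 up and 3553 down, of which 712 and 315 changed at least 2-fold. The libraries did not overlap in 56.7% of genes, and the share of called genes that rose was 45.7%, or 57.4% with library size alone.

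**Figure D3:**
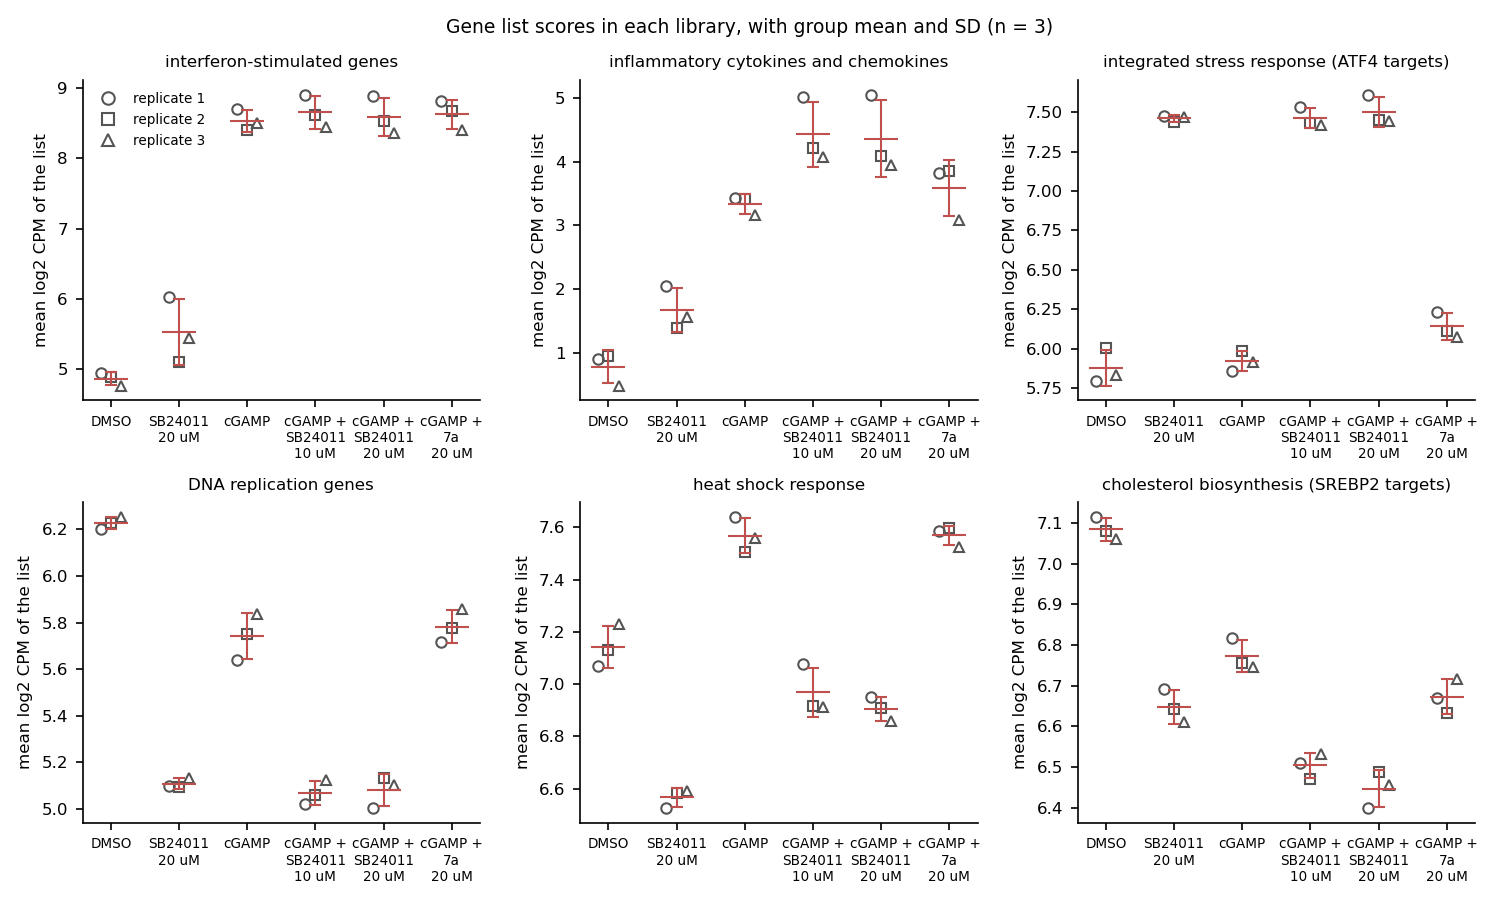
Mean log2 CPM over the members of 6 gene lists in each library, with the group mean and SD (n = 3). The interferon-stimulated gene score is 8.53 with cGAMP and between 8.59 and 8.66 when SB24011 or 7a is added, while the stress response score is higher in each group with SB24011.

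Adding 20 uM SB24011 to cGAMP, compared with cGAMP alone, asks whether the compound changed the response to the STING agonist. The interferon response as a whole did not move detectably. Of 60 interferon-stimulated genes 2 rose (Oas1g and Xaf1) and 3 fell (Oas2, Eif2ak2 and Phf11d), or 2 and 1 over the list alone, and the list did not pass (camera adjusted p = 0.943). Its score was 8.53 ± 0.152 with cGAMP and 8.59 ± 0.273 with both (log2 CPM, SD, n = 3, exact permutation p = 0.8). Cxcl10 stood at 1126 ± 133 CPM without and 1194 ± 192 CPM with SB24011 (0.08 ± 0.31 SE, 95% interval -0.58 to 0.74, adjusted p = 0.851), and Isg15 at 490 ± 56.1 and 494 ± 98.8 (0.01 ± 0.20, interval -0.42 to 0.44, adjusted p = 0.97). Ifit1 was not called (0.27 ± 0.29, adjusted p = 0.481) except in a fit of the 2 groups alone (adjusted p = 0.04). Ifnb1 itself rose, from 2.08 ± 0.261 to 4.07 ± 0.913 CPM (0.96 ± 0.31, adjusted p = 0.0181). That call ended without cGAMP replicate 3 (0.88, adjusted p = 0.0686), without replicate 1 of the combined group (0.77, 0.082) and without library set 1 (0.87, 0.101).

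Several inflammatory cytokine genes were higher with SB24011 on cGAMP. Il6 (chromosome 5, 30013114 to 30019975) rose from 0.331 ± 0.109 to 9.31 ± 4.77 CPM (4.77 ± 0.48, adjusted p = 2.76e-06), Csf3 by 3.79 ± 0.59 and Tnf (chromosome 17, 35199367 to 35202007) from 282 ± 13.5 to 496 ± 113 CPM (0.81 ± 0.16, adjusted p = 0.000678). Il1a had no read with cGAMP alone and was at least 47.5-fold higher, with an SD above its mean (1.02 ± 1.28 CPM). Of 29 cytokine and chemokine genes 11 rose and none fell, the same over the list alone (median 0.46, camera adjusted p = 0.0299, 0.924 with an estimated correlation). Without cGAMP replicate 3 the adjusted p was 0.0781, without replicate 1 of the combined group 0.144 (median 0.125), and without library set 1 0.0859. The median was 0.778 without cGAMP replicate 2 and 0.72 without replicate 3 of the combined group. Of 41 NF-kB genes 14 rose and 3 fell, the same over the list alone (camera adjusted p = 0.027, 0.924 with an estimated correlation). Nfkbiz rose by 2.06 ± 0.26 and Bcl2a1b by 1.81 ± 0.18. This list lost its call without cGAMP replicate 2 (0.0648), cGAMP replicate 3 (0.0676) or replicate 1 of the combined group (0.205). Tmem173 fell from 46.5 ± 8.81 to 27.4 ± 4.80 CPM (-0.77 ± 0.15, adjusted p = 0.00072).

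Other groups of genes moved with 20 uM SB24011 on cGAMP as follows. Of 38 integrated stress response genes 37 rose and none fell, the same over the list alone, with a median of 1.31 (camera adjusted p = 7.44e-71, 0.000922 with an estimated correlation). Gdf15 rose by 4.65 ± 0.32, Trib3 by 3.56 ± 0.22 and Cth by 3.30 ± 0.13. Of 45 DNA replication genes 37 fell and 1, Pold1, rose (38 and 1 over the list alone), with a median of -0.65 (camera adjusted p = 1.5e-23, 0.0469 with an estimated correlation). Ccne2 fell by 2.13 ± 0.16, E2f7 by 1.79 ± 0.12 and Ccne1 by 1.39 ± 0.15. Hspa1a fell by 3.34 ± 0.33, Hspa8 by 1.16 ± 0.11 and Hsph1 by 1.07 ± 0.11. Of 26 heat shock genes 17 fell and 1, Ubb, rose (19 and 2 over the list alone, camera adjusted p = 7.11e-09, 0.106 with an estimated correlation). Of 40 mitotic genes 30 fell (32 over the list alone) and none rose, with Mki67 at -0.66 ± 0.09 (camera adjusted p = 7.11e-09, 0.602 with an estimated correlation). Of 25 cholesterol biosynthesis genes 17 fell and 1, Mvk, rose (19 and 1 over the list alone), with Hmgcs1 at -0.84 ± 0.06 (camera adjusted p = 9.33e-08, 0.133 with an estimated correlation).

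Ribosome biogenesis genes fell in 23 of 36 cases and rose in 4 with SB24011 on cGAMP (27 and 4 over the list alone, camera adjusted p = 9.99e-06, 0.774 with an estimated correlation). Polr1b fell by 0.92 ± 0.10 and Myc rose by 1.96 ± 0.29. Of 42 lysosome and autophagy genes 20 rose and 5 fell (22 and 6 over the list alone) (camera adjusted p = 0.00427, 0.225 with an estimated correlation). Sqstm1 rose by 2.08 ± 0.11 and Npc1 by 0.81 ± 0.06, while Gabarapl1 fell by 0.79 ± 0.07. Of 64 ribosomal protein genes 26 rose by small amounts, the same over the list alone, with Rpl10a at 0.34 ± 0.05 (camera adjusted p = 0.0299, 0.924 with an estimated correlation). This call ended without cGAMP replicate 2 (0.095) or replicate 1 of the combined group (0.0725). The NRF2 list, with 13 of 37 up and 3 down, the same over the list alone, missed the threshold (0.0555). It passed without library set 1 (0.0227), without cGAMP replicate 2 (0.00397) and without replicate 1 of the combined group (0.0143). Outside the lists Extl1 rose by 5.05 ± 0.31, Aqp9 by 4.43 ± 0.31 and Adh7 by 4.34 ± 0.40. Tgif2 fell by 2.14 ± 0.19 and Kbtbd11 by 2.12 ± 0.15. Over all genes edgeR called 6201, 3180 up and 3021 down, with 674 and 263 at 2-fold or more. The libraries did not overlap in 49.5% of genes.

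At 10 uM SB24011 on cGAMP, compared with the same cGAMP libraries, 9 of the 10 lists that passed at 20 uM passed. Ribosomal protein genes did not (median 0.01, camera adjusted p = 0.94, 1 up and 1 down). Il6 rose by 4.59 ± 0.48 (SE), Gdf15 by 4.27 ± 0.32, Trib3 by 3.39 ± 0.22 and Tnf by 0.85 ± 0.16 (adjusted p = 0.000517), and Tmem173 fell by 0.69 ± 0.15 (adjusted p = 0.0018). Ifnb1 was not called (2.82 ± 0.378 CPM, 0.43 ± 0.31, adjusted p = 0.288), nor were Cxcl10 (0.14 ± 0.31, adjusted p = 0.759) and Isg15 (-0.01 ± 0.20, adjusted p = 0.986). Ifit1 was called only in a fit of the 2 groups alone (0.27 ± 0.29, adjusted p = 0.493, and 0.0251 in that fit). Of 60 interferon-stimulated genes 2 rose (Oas1g and Xaf1) and 1 fell (Eif2ak2), the same over the list alone, and the list did not pass (camera adjusted p = 0.817, score 8.66 ± 0.234, exact permutation p = 0.6). Of 38 integrated stress response genes 37 rose, the same over the list alone (median 1.28, camera adjusted p = 1.21e-74, 0.000646 with an estimated correlation). DNA replication genes fell in 37 of 45 cases, or 38 with 1 up over the list alone (median -0.66, camera adjusted p = 3.92e-27, 0.03 with an estimated correlation), with Ccne2 at -2.18 ± 0.16 and Rrm2 at -1.36 ± 0.16. The 2 comparisons share the cGAMP libraries, so part of their likeness can come from these.

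The other lists that passed at 10 uM lost their calls with an estimated correlation. Of 40 mitotic genes 31 fell, the same over the list alone, with Ccnf at -0.86 ± 0.08 (camera adjusted p = 1.42e-09, 0.538 with an estimated correlation). Of 26 heat shock genes 18 fell and 1 rose, the same over the list alone, with Hspa1a at -2.73 ± 0.31 (7.43e-09, 0.103 with an estimated correlation). Of 25 cholesterol biosynthesis genes 18 fell and 1 rose (18 and 2 over the list alone), with Stard4 at -0.77 ± 0.09 (2.34e-06, 0.227 with an estimated correlation). Of 36 ribosome biogenesis genes 23 fell and 3 rose (26 and 4 over the list alone), with Polr1b at -0.84 ± 0.09 (5.82e-06, 0.737 with an estimated correlation). NF-kB genes rose in 16 of 41 cases and fell in 2 (16 and 3 over the list alone), with Nfkbiz at 2.16 ± 0.26 (0.0103, 0.981 with an estimated correlation, 0.125 without replicate 1 of the combined group). Cytokine and chemokine genes rose in 10 of 29 cases, the same over the list alone, with Csf3 at 3.56 ± 0.59 (0.0195, 0.981 with an estimated correlation, 0.053 without cGAMP replicate 3 and 0.11 without replicate 1 of the combined group). Lysosome and autophagy genes rose in 19 of 42 cases and fell in 4, the same over the list alone, with Sqstm1 at 1.93 ± 0.11 (0.0213, 0.468 with an estimated correlation, 0.0512 without cGAMP replicate 3 and 0.0561 without replicate 1 of the combined group). Over all genes edgeR called 5708, 2910 up and 2798 down, with 613 and 189 at 2-fold or more. In 50.5% of genes the libraries did not overlap.

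**Figure D4:**
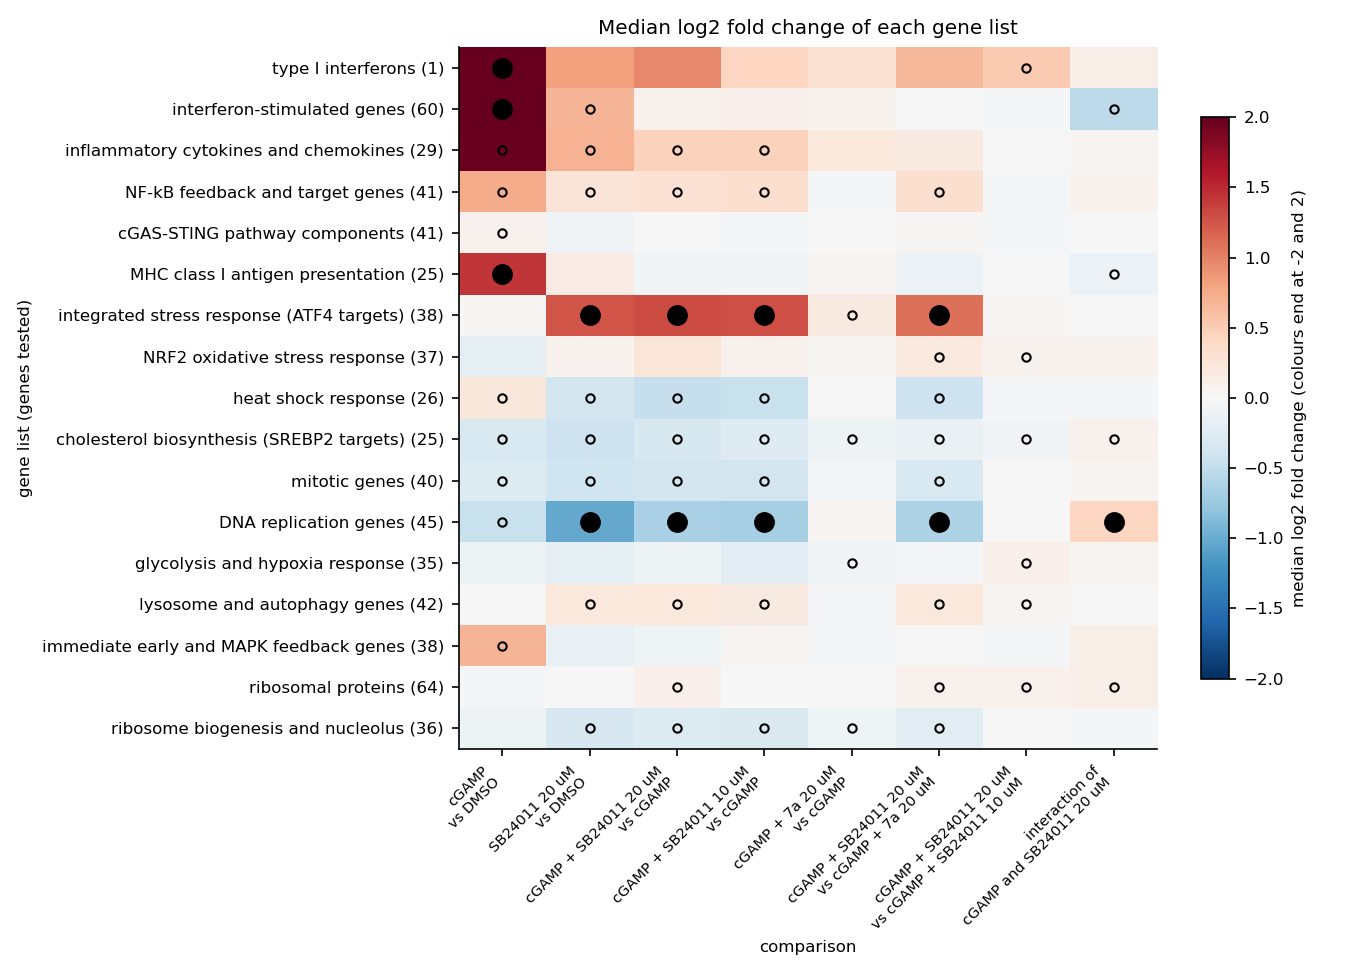
Median log2 fold change of the 17 gene lists that passed camera in any comparison, by comparison, with colours ending at -2 and 2. A small open circle marks a camera adjusted p under 0.05 and a large filled circle one that also passed with an estimated correlation, which the stress response and DNA replication lists did in each comparison of SB24011 with a group lacking it.

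The analog 7a on cGAMP, compared with cGAMP alone, serves as the series' negative control for SB24011. No gene was called by edgeR (smallest adjusted p = 0.101, with 1208 genes at an unadjusted p under 0.05). DESeq2 called 38 genes, 20 up and 18 down, edgeR with the library set as a replicate block called 8, 4 each way, and edgeR without replicate 3 of the 7a group called 48, 18 up and 30 down. Tnf stood at 282 ± 13.5 CPM (SD, n = 3) with cGAMP and 288 ± 4.18 with 7a added (0.03 ± 0.16 SE, 95% interval -0.31 to 0.36), Tmem173 at 46.5 ± 8.81 and 45.6 ± 4.03 (-0.03 ± 0.15, interval -0.35 to 0.29) and Il6 at 0.331 ± 0.109 and 0.867 ± 0.359 (1.36 ± 0.51, interval 0.25 to 2.46, adjusted p = 0.525). Ifnb1 (0.31 ± 0.31, interval -0.34 to 0.97), Cxcl10 (0.36 ± 0.31, -0.30 to 1.02), Ifit1 (0.24 ± 0.29, -0.38 to 0.85) and Isg15 (0.10 ± 0.20, -0.34 to 0.53) were not called. The interval lay within 2-fold either way for 80.7% of genes and within 1.5-fold for 68.7%. The libraries did not overlap in 12.7% of genes, where chance gives 10%.

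As lists, small shifts passed camera with 7a on cGAMP, and none passed with an estimated correlation. The integrated stress response list had a median of 0.18 (camera adjusted p = 2.11e-17, 0.196 with an estimated correlation), with no member called over all genes and 10 up over the list alone. Cholesterol biosynthesis genes had a median of -0.10 with 7 down over the list alone (8.01e-07, 0.326 with an estimated correlation). Ribosome biogenesis genes had a median of -0.08 with 3 down over the list alone (1.42e-05, 0.989 with an estimated correlation). The median was -0.127 and -0.052 without cGAMP replicates 1 and 2, -0.142 without 7a replicate 3, and -0.021 without 7a replicate 1, where the call ended (0.224). Glycolysis and hypoxia genes had a median of -0.07 with none called over the list alone (0.0413, 0.989 with an estimated correlation). That call ended without cGAMP replicate 1 (0.262), without 7a replicate 1 (0.127), without 7a replicate 2 (0.768, median -0.044), with library size alone (0.0618) and without library set 1 (0.405). The median was -0.11 without cGAMP replicate 2 and -0.119 without 7a replicate 3. The interferon-stimulated gene list did not pass (median 0.07, camera adjusted p = 0.137, score 8.63 ± 0.206, exact permutation p = 0.6). It did without cGAMP replicate 1 (0.00151, median 0.143), without 7a replicate 3 (0.00326, median 0.138) and without library set 1 (0.015). The median was 0.022 without cGAMP replicate 2 and -0.005 without 7a replicate 1. The cytokine list, at 0.105, passed with the replicate block (0.0452), without cGAMP replicate 1 (0.0458), without 7a replicate 3 (0.00326) and without library set 1 (0.0468). Mitotic genes passed downward without cGAMP replicate 2 (0.00107), 7a replicates 1 (0.0118) or 3 (0.0212) and without library set 1 (0.015). DNA replication genes passed upward without cGAMP replicate 3 (7.1e-05) or 7a replicate 1 (0.000602), MHC class I genes without cGAMP replicate 1 (0.00679) or library set 1 (0.0139) and ribosomal protein genes without 7a replicate 2 (0.00218).

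SB24011 against 7a, both at 20 uM on cGAMP for 6 h, is the direct test of the difference between the compounds. Gdf15 was higher with SB24011 by 4.35 ± 0.31 (log2, SE), Trib3 at 221 ± 12.2 against 26.1 ± 4.67 CPM (SD, n = 3) by 3.08 ± 0.21 and Sqstm1 at 2246 ± 198 against 543 ± 62.7 CPM by 2.05 ± 0.11. Il6 was higher by 3.42 ± 0.42 (adjusted p = 2.72e-05) and Tnf by 0.78 ± 0.16 (adjusted p = 0.00111), while Tmem173 was lower (-0.74 ± 0.15, adjusted p = 0.00123). Ccne2 (-2.36 ± 0.16), Hspa1a (-3.43 ± 0.33) and the zinc transporter gene Slc39a10 (-1.89 ± 0.12) were lower. Car6 had no read with 7a and was at least 215-fold higher with SB24011, and Angptl6 (3.99 ± 0.20) and Cox6a2 (3.85 ± 0.75) were higher. Cxcl10 (-0.27 ± 0.31, 95% interval -0.93 to 0.39, adjusted p = 0.541), Isg15 (-0.09 ± 0.20, -0.52 to 0.35, adjusted p = 0.79) and Ifit1 (0.04 ± 0.29, -0.58 to 0.65, adjusted p = 0.946) did not differ detectably. Ifnb1 was not called (0.65 ± 0.30, interval 0.01 to 1.29, adjusted p = 0.107), but was with DESeq2 (0.0204), in a fit of the 2 groups alone (0.0447) and with the library set as a block (0.0334).

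By list, 36 of 38 integrated stress response genes were higher with SB24011 than with 7a (37 over the list alone, median 1.10, camera adjusted p = 1.19e-64, 0.00127 with an estimated correlation). Also, 39 of 45 DNA replication genes were lower (41 over the list alone, median -0.62, 5.91e-33, 0.0137 with an estimated correlation). Of 26 heat shock genes 18 were lower and 1 higher (20 and 1 over the list alone, 3.07e-10, 0.0675 with an estimated correlation). Of 40 mitotic genes 27 were lower (29 over the list alone, 1.4e-08, 0.627 with an estimated correlation), and of 25 cholesterol biosynthesis genes 12 were lower and 1 higher (12 and 2 over the list alone, 5.39e-05, 0.309 with an estimated correlation). Lysosome and autophagy genes were higher in 20 of 42 cases and lower in 4 (22 and 5 over the list alone, 0.000569, 0.134 with an estimated correlation). Ribosome biogenesis genes were lower in 20 of 36 and higher in 4 (21 and 4 over the list alone, 0.00117, 0.871 with an estimated correlation). NF-kB genes were higher in 15 of 41 cases and lower in 2, the same over the list alone (0.00855, 0.871 with an estimated correlation, 0.119 without SB24011 replicate 1). NRF2 genes were higher in 12 of 37 cases and lower in 2 (12 and 3 over the list alone, 0.0315, 0.871 with an estimated correlation, 0.133 without 7a replicate 1 and 0.0985 without SB24011 replicate 2), the metallothionein gene Mt2 among them (1.76 ± 0.45). Ribosomal protein genes were higher in 16 of 64 cases (4 over the list alone), with Rpl12 at 0.24 ± 0.05 (0.0421, 0.871 with an estimated correlation). That call ended without 7a replicate 2 (0.264), without SB24011 replicate 1 (0.0946), with RLE (0.0597) and without library set 1 (0.0809). The interferon-stimulated gene list did not pass (2 up and 1 down, 1 and 1 over the list alone, 0.663, score difference -0.04, exact permutation p = 0.9). The cytokine list, with 10 of 29 higher and none lower, the same over the list alone, missed the threshold (0.067). It passed without 7a replicate 2 (0.0459) and without SB24011 replicates 2 (0.0247) or 3 (0.00887). Over all genes edgeR called 5336, 2886 higher and 2450 lower with SB24011, of which 537 and 172 differed at least 2-fold. In 42.9% of genes the libraries did not overlap.

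The comparison of 20 with 10 uM SB24011, both on cGAMP, asks whether the response depended on dose in this range. No gene was called by edgeR (smallest adjusted p = 0.52, with 404 genes at an unadjusted p under 0.05) or by DESeq2, and the libraries did not overlap in 7.04% of genes. Il6 stood at 8.18 ± 3.06 CPM (SD, n = 3) with 10 uM and 9.31 ± 4.77 with 20 uM (0.19 ± 0.36 SE, 95% interval -0.60 to 0.96), Tnf at 509 ± 105 and 496 ± 113 (-0.04 ± 0.16, interval -0.37 to 0.30) and Ifnb1 at 2.82 ± 0.378 and 4.07 ± 0.913 (0.53 ± 0.30, interval -0.11 to 1.16). Tmem173 (-0.08 ± 0.15, -0.40 to 0.25), Cxcl10 (-0.05 ± 0.31, -0.71 to 0.61), Ifit1 (0.00 ± 0.29, -0.61 to 0.62) and Isg15 (0.02 ± 0.20, -0.41 to 0.45) were not called. The interval lay within 2-fold for 82.6% of genes and within 1.5-fold for 71.4%.

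Shifts of whole lists between the doses were small, and none of the 6 that passed camera did so with an estimated correlation. Ribosomal protein genes were higher at 20 uM by a median of 0.09 (camera adjusted p = 3.23e-27, 0.244 with an estimated correlation, 1 up over the list alone), alone among the 6 in passing without each library in turn. Glycolysis and hypoxia genes had a median of 0.10 (3.43e-05, 0.554 with an estimated correlation). It was 0.161 without replicate 1 of the 20 uM group and 0.033 without replicate 3, where the call ended (0.162). Cholesterol biosynthesis genes had a median of -0.05 (0.00293, 0.554 with an estimated correlation), and the call ended without replicate 3 of the 10 uM group (0.0751), replicate 1 of the 20 uM group (0.323, median -0.035) or library set 1 (0.252). The median was -0.034 and -0.082 without replicates 1 and 2 of the 10 uM group. NRF2 genes had a median of 0.07 (0.0121, 0.954 with an estimated correlation), and the call ended without replicate 1 of the 10 uM group (0.401, median 0.041) or replicates 2 (0.51, median 0.022) or 3 (0.0568) of the 20 uM group. The median was 0.117 without replicate 1 of the 20 uM group. Lysosome and autophagy genes had a median of 0.05 (0.0138, 0.522 with an estimated correlation), with 0.193 without replicate 3 of the 10 uM group, and 0.0947 and 0.122 (median 0.032) without replicates 1 and 2 of the 20 uM group. The type I interferon list had 0.0295 (0.244 in the test repeated with an estimated correlation), although the test of single genes did not call Ifnb1. With Ifnb1 as its 1 member the list has no inter-gene correlation to estimate. The adjusted p of the list was 0.0827 and 0.118 without replicates 2 and 3 of the 10 uM group. It was 0.207 without replicate 1 of the 20 uM group (0.33 in place of 0.53) and 0.0859 without library set 1. The interferon-stimulated gene list did not pass (median -0.04, camera adjusted p = 0.198, score difference -0.06, exact permutation p = 0.7). It did, downward, without replicate 3 of the 10 uM group (0.000272), without replicate 1 of the 20 uM group (2.16e-06) and without library set 1 (0.00288). Other lists passed without single libraries, 3 of them in opposite directions. NF-kB genes passed upward without replicate 1 of the 10 uM group (0.216, 4.31e-05) and downward without its replicates 2 (-0.131, 0.0222) and 3 (-0.136, 0.00519) and without replicate 1 of the 20 uM group (-0.273, 1.55e-07). Cytokines passed upward without replicate 1 of the 10 uM group (0.273, 0.0031) and downward without its replicate 3 (-0.134, 0.0423) and replicate 1 of the 20 uM group (-0.303, 0.000214). Mitotic genes passed downward without replicate 1 of the 10 uM group (-0.04, 0.00773) and replicate 2 of the 20 uM group (-0.026, 0.0295), and upward without replicate 1 of the 20 uM group (0.071, 0.000214). DNA replication, MHC class I, heat shock, immediate early, integrated stress response and ribosome biogenesis genes each passed in 1 to 3 of the 6 fits, in 1 direction each.

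The interaction asks whether the change with 20 uM SB24011 differed with and without cGAMP. DNA replication genes fell less on cGAMP than without it, by a median of 0.43 on the log2 scale, and 12 of 45 differed by themselves, each in this direction (37 over the list alone, camera adjusted p = 2.92e-50, 0.0042 with an estimated correlation). Cdc6 went from 51.8 ± 5.65 to 10.5 ± 1.03 CPM (SD, n = 3) without cGAMP and from 24.6 ± 2.87 to 10.2 ± 1.12 CPM on it (interaction 1.04 ± 0.17 SE, adjusted p = 0.0104). Timeless, a replication fork protein gene, fell from 52.4 ± 3.05 to 40.3 ± 4.44 CPM without cGAMP and rose from 98.1 ± 2.12 to 140 ± 18 on it (0.89 ± 0.13, adjusted p = 0.00389). Dtl (0.64 ± 0.10, adjusted p = 0.00469, a span shared with Ints7) and Ctnnal1 (1.26 ± 0.18, adjusted p = 0.00389) fell less on cGAMP. These calls ended without library set 1 (adjusted p = 0.0664 and 0.0968), and that of Ctnnal1 also with limma (0.0581). Mcm10 (0.67 ± 0.12, adjusted p = 0.0172) lost its call without DMSO replicate 1 (0.0628), cGAMP replicates 1 (0.0712) or 2 (0.0553) or SB24011 replicate 3 (0.0629), in a fit of the compared groups alone (0.0976) and with limma (0.0608).

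On the log2 scale the largest differences in the other direction were in genes that both treatments raised. LOC101055758 (chromosome 1, 85326832 to 85555681) stood at 7.17 ± 1.30 CPM in DMSO, 50.8 ± 2.89 with SB24011, 67.3 ± 1.11 with cGAMP and 120 ± 10.2 with both (interaction -1.98 ± 0.13, adjusted p = 4.49e-07). Gm7609, Gm7582 and Gm38510 lie in the same stretch of chromosome 1 and gave -1.996, -1.86 and -1.74, and Gm4070 on chromosome 7 (105895118 to 105953967) gave -1.42. Gene copies in these stretches resemble each other, and how reads with several positions were counted is not given in the sources used here. As a list, interferon-stimulated genes had a lower log2 change with SB24011 on cGAMP, where no rise was detected, than without it (median -0.53, camera adjusted p = 1.72e-29, but 0.622 with an estimated correlation), with none called over all genes and 12 down over the list alone. Isg15 was called with the library set as a block (-0.885, adjusted p = 0.0427) and Ifit1 without SB24011 replicate 2 (-1.628, 0.00588). Without SB24011 replicate 1 the median of the list was -0.297. The rise with SB24011 alone was small beside that with cGAMP. Its median share of the cGAMP rise in CPM over 57 members was 7.45%, 0.927% and 3.72% in replicates 1, 2 and 3. An equal rise in CPM on cGAMP would be a small log2 change for most members. The list therefore does not show that cGAMP removed the rise. Ribosomal protein genes (median 0.11, 4.04e-08, 0.688 with an estimated correlation) and MHC class I genes (median -0.13, 0.000227, 0.709 with an estimated correlation) passed with no member called either way. The MHC class I median was -0.234 and -0.082 without replicates 1 and 2 of the combined group. Cholesterol biosynthesis genes (median 0.09, 0.0328, 0.709 with an estimated correlation) had 3 up over the list alone, and kept the call without 5 of 12 libraries. It ended without DMSO replicate 1 (0.128), cGAMP replicates 2 (0.0603) and 3 (0.165), SB24011 replicates 2 (0.0624) and 3 (0.185), replicates 2 (0.173) and 3 (0.06) of the combined group, with RLE (0.0897) and with library size alone (0.0931). The heat shock list did not pass, but did downward without DMSO replicates 2 (0.0387) or 3 (0.00971), cGAMP replicate 2 (0.0375), SB24011 replicate 1 (0.0044) or replicate 2 of the combined group (0.00334), and with library size alone (0.0377). The integrated stress response passed downward without DMSO replicate 2 (0.0209) or replicate 1 of the combined group (0.033), and ribosome biogenesis without SB24011 replicate 1 (0.0221) or replicate 2 of the combined group (0.0287). Without replicate 1 of the combined group NF-kB genes (0.00876) and cytokines (0.0272) passed downward and mitotic genes upward (0.00797, and 0.0317 without library set 1).

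edgeR called 54 genes for the interaction, 36 higher and 18 lower, with 1312 at an unadjusted p under 0.05, and of these 3 and 15 differed at least 2-fold. The count moved by more than 1.5 times without DMSO replicate 1 (33) or 3 (29), cGAMP replicate 1 (23), SB24011 replicate 3 (31) or replicate 2 of the combined group (33). It was 33 with library size alone, where 30.3% were higher in place of 66.7%, 321 with the library set as a block, 23 without library set 1, 29 in a fit of the compared groups alone and 173 with DESeq2. The direct changes were otherwise alike: over 14650 genes the log2 fold changes of SB24011 without and with cGAMP, which share no library, had a Pearson r of 0.665 and a Spearman rho of 0.797 (across genes, which are not independent replicates). Genes called up in both numbered 2340, where independent lists would share 649, genes called down in both 2596 against 733, and 6 genes were called in opposite directions.

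**Figure D5:**
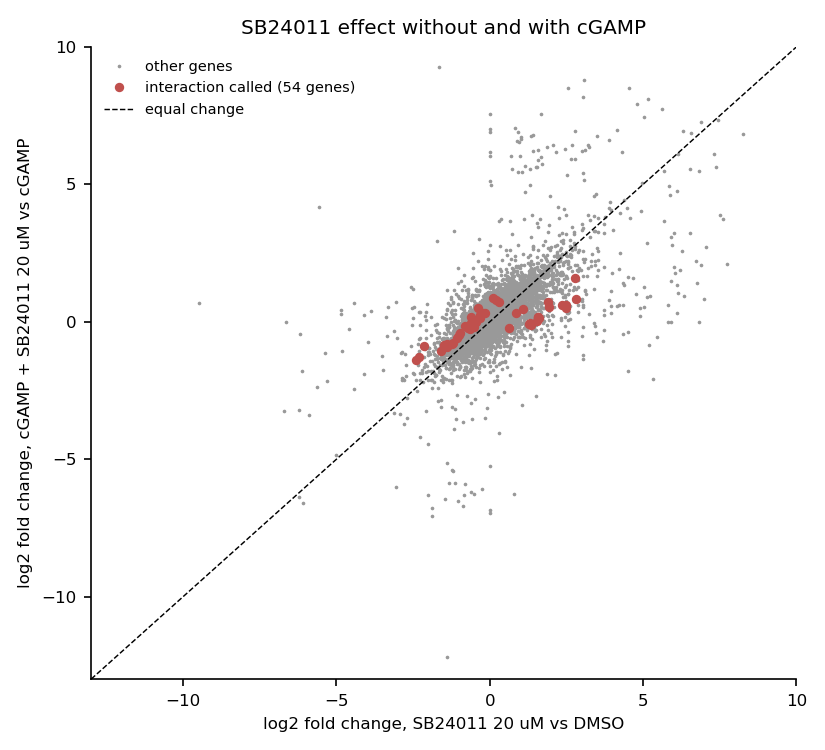
Log2 fold change with 20 uM SB24011 without cGAMP (horizontal) and on cGAMP (vertical) for each of the 14650 genes, with the 54 interaction genes in red and equal change as a dashed line. Pearson's r is 0.665 across genes.

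The remaining lists passed camera in none of the 8 comparisons. The lowest camera adjusted p was 0.45 for MHC class II genes (20 against 10 uM), 0.247 for the unfolded protein response (7a on cGAMP), 0.0998 for LXR and fatty acid synthesis genes, 0.242 for transcripts of the mitochondrial genome, 0.0588 for macrophage identity genes and 0.0884 for markers of other cell types (each cGAMP against DMSO), 0.231 for p53 targets (the interaction) and 0.0603 for AhR targets (SB24011 against 7a). Without single libraries several of these passed. Transcripts of the mitochondrial genome passed downward for the doses (4.42e-09), for 20 uM SB24011 on cGAMP (0.00896) and for SB24011 against 7a (0.0232), each without replicate 2 of the 20 uM group. With 7a they passed downward without cGAMP replicate 3 (0.0383) or 7a replicate 2 (0.0398). For the doses the unfolded protein response passed without replicate 2 of the 10 uM group (0.000356) and replicate 3 of the 20 uM group (0.0155), MHC class II without replicate 1 of the 10 uM group (0.0234) and LXR genes without replicate 2 of the 20 uM group (0.0185). The AhR list passed for SB24011 against 7a without 7a replicate 2 (0.00866) and without SB24011 replicate 3 (0.041), and in the interaction without DMSO replicate 3 (0.0302) or SB24011 replicate 1 (0.0386). Of 30 macrophage identity genes 11 rose and 4 fell with cGAMP (13 and 4 over the list alone). The list passed with library size alone (0.033), without library set 1 (0.0291), without cGAMP replicate 3 (0.0182) and without DMSO replicate 2 (0.0382). Only 3 markers of other cell types had enough reads to test, of which Kdr (3.13) and Cdh5 (2.15), named after their values were seen, rose with cGAMP, and the list passed with library size alone (0.0409).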

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

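The results in this part are, with 1 exception said below, differences between the change with SB24011 on cGAMP and the change with SB24011 alone, each found by the interaction test. The tests of the 3 weighed patterns were chosen after their results were seen, while the counts over other splits of the libraries were planned before.

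edgeR called 54 genes for the interaction. Of 60 drawn splits of the 12 libraries 6, the real one included, called as many. The count neither excludes chance nor argues for it, since exchanged labels can carry the effect of SB24011 itself into the interaction. The highest other split called 8357 genes, which points to a structure of the samples: each of the 5 other splits keeps at least 2 of 3 DMSO labels and exchanges SB24011 labels among the cGAMP libraries, so it carries the effect of SB24011 itself. The highest of the remaining splits called 51. It too kept the DMSO labels and exchanged SB24011 labels among the cGAMP libraries, so the same holds. The count was 33 without DMSO replicate 1, 29 without DMSO replicate 3, 23 without cGAMP replicate 1, 31 without SB24011 replicate 3 and 33 without replicate 2 of the combined group. With the library set as a block it was 321.

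Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real split was the 1 with the most genes in cGAMP against DMSO (5193, highest other 0), SB24011 alone against DMSO (6541, highest other 0), 20 uM SB24011 on cGAMP (6201, highest other 1), 10 uM (5708, highest other 0) and SB24011 against 7a (5336, highest other 0). For 7a on cGAMP and for the doses 10 of 10 splits called as many, which a real count of 0 fixes in advance. The highest others were 2 and 1. In SB24011 alone against DMSO and 7a on cGAMP the library numbers pair the samples. There 3 other splits part each of the 3 pairs, with 0 genes called, and the 6 others part 1 pair. The splits were fitted without the library set as a block. In a split that mixes treated and untreated libraries the treatment effect also adds to the spread, which holds its count down. The zero for 7a stands beside 1208 genes at an unadjusted p under 0.05. It also stands beside 8 genes called with the block, 38 by DESeq2 and 48 without replicate 3 of the 7a group. The zero for the doses stands beside 404 genes at an unadjusted p under 0.05 and, by DESeq2, 0 called.

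DNA replication genes fell less with SB24011 on cGAMP than with SB24011 alone (median difference 0.432, camera adjusted p = 0.0042 with an estimated correlation). The tables argue against a single library, since the lowest median without any of the 12 libraries was 0.372. The median levels were 72.8 CPM in DMSO, 47.3 with cGAMP, 35.2 with SB24011 and 34.8 with both, but members differ: Mcm10 stood at 69.9, 126, 40 and 114 CPM. What makes the falls differ was not tested and stays open.

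Interferon-stimulated genes had a lower log2 change with SB24011 on cGAMP than with SB24011 alone (median difference -0.53, or -0.297 without SB24011 replicate 1, camera adjusted p = 0.622 with an estimated correlation). On cGAMP no rise of the list was detected, but an equal rise in CPM would be a small log2 change there for most members. The rise with SB24011 alone is the pattern weighed here. Carry-over of cGAMP-treated material into the SB24011 libraries would give each gene the same share of its cGAMP rise. Against carry-over as the only source, 18 of 57 members differed over 2 times from the median share of the library in the same direction in 3 of 3 libraries, among them Oas1g at 39.8% and Iigp1 at 0.677% on average. The shares cannot tell whether carry-over contributed beside effects of SB24011 itself. A single library is argued against by the list score, whose difference from DMSO, 0.664, was at its lowest, 0.411, without SB24011 replicate 1. What stays open is the adjusted p of 0.929 with an estimated correlation for the rise itself, so a response of the cells to SB24011 may be the source and remains a hypothesis.

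The third pattern, in the 7a comparison, is not an interaction: integrated stress response genes rose as a list with 7a on cGAMP (median 0.18). A single library is argued against by the highest camera adjusted p without each of 6 libraries, 7.67e-11. Carry-over of SB24011-treated material would give each gene 1 share of its SB24011 rise, and stays open: the median share was 7.8% for the list and 5.44% for other raised genes, and for 13 of 209 genes the share differed from 7.8% beyond its 95% interval, where 10.5 were expected. Of 21 genes raised from a low level on cGAMP 5 had an interval below 7.8% and 0 above it, but this subset was picked, and its cutoffs set, after the values were seen, so it excludes nothing. Weak activity of 7a itself, not tested, stays open too, as do list members that vary together between libraries, since the adjusted p was 0.196 with an estimated correlation.

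As lists, MHC class I genes differed by a median of -0.125 (-0.234 and -0.082 without replicates 1 and 2 of the combined group), ribosomal protein genes by 0.114 and cholesterol biosynthesis genes by 0.085 (camera adjusted p = 0.000227, 4.04e-08 and 0.0328, with an estimated correlation 0.709, 0.688 and 0.709). The cholesterol call ended without DMSO replicate 1 (0.128), cGAMP replicates 2 (0.0603) and 3 (0.165), SB24011 replicates 2 (0.0624) and 3 (0.185) and replicates 2 (0.173) and 3 (0.06) of the combined group. No explanation of these shifts was tested.

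Single genes with a higher change on cGAMP were Ctnnal1 (1.258), Cdc6 (1.04), Ccne1 (1.029), Timeless (0.892), Rps6ka5 (0.791), Rftn1 (0.76), Mcm10 (0.667), Dtl (0.642) and Chaf1a (0.593). Genes with a lower change on the log2 scale were Gm7609 (-1.996), LOC101055758 (-1.983), Gm7582 (-1.858), Gm38510 (-1.744), 9130208D14Rik (-1.528), Gm8979 (-1.462), Gm1966 (-1.454) and Gm4070 (-1.422). Gm7609, LOC101055758, Gm7582 and Gm38510 lie in a stretch of chromosome 1 and the others in a stretch of chromosome 7. Gene copies in these stretches resemble each other, and Gm38510 overlaps Gm7609 on the map, so their calls may not be independent. A lower log2 change was not always a smaller rise in CPM. With SB24011 Gm7609 went from 7.61 to 42.7 CPM without cGAMP and from 106 to 149 on it. By contrast, 9130208D14Rik went from 6.55 to 19.2 CPM without cGAMP and from 84 to 85.2 on it. Without library set 1 the calls of Ctnnal1 (0.0968), Dtl (0.0664), Gm1966 (0.0754) and Chaf1a (0.0754) ended, as did those of Ccne1 (0.0555), Rps6ka5 (0.105) and Rftn1 (0.105), and with limma those of Ctnnal1 (0.0581), Mcm10 (0.0608), Rps6ka5 (0.0764) and Gm8979 (0.0764). RLE ended the calls of Ccne1 (0.0636) and Rps6ka5 (0.0634), and library size alone those of Ccne1 (0.0597), Rps6ka5 (0.108) and Rftn1 (0.0691). The fit of the compared groups ended those of Ccne1 (0.167), Rps6ka5 (0.127), Rftn1 (0.0969) and Mcm10 (0.0976). Of these 17 genes 4 lost their call without single libraries. For Ccne1 the adjusted p was 0.0885 and 0.114 without DMSO replicates 2 and 3, 0.137 and 0.0931 without cGAMP replicates 1 and 2, 0.0663 and 0.0576 without SB24011 replicates 1 and 3, and 0.0997 and 0.0637 without replicates 2 and 3 of the combined group. For Rps6ka5 it was 0.102 and 0.0949 without DMSO replicates 1 and 3, 0.137 and 0.0931 without cGAMP replicates 1 and 2, 0.0893 and 0.109 without SB24011 replicates 2 and 3, and 0.105 and 0.0984 without replicates 2 and 3 of the combined group. For Rftn1 it was 0.0678 and 0.0621, 0.0517 and 0.0631, 0.065 and 0.0576, and 0.0597 and 0.0598 without the same 8 libraries. Mcm10 had 0.0628 without DMSO replicate 1, 0.0712 and 0.0553 without cGAMP replicates 1 and 2, and 0.0629 without SB24011 replicate 3.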

How the results depend on the processing

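Scaling by library size alone and the fit without library set 1 (libraries 1 to 6) were chosen after seeing the data. The other alternatives were chosen before the data were examined.

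Requiring at least 2-fold in place of any change left 1101 genes for cGAMP against DMSO, 1027 for SB24011 alone, 937 for 20 uM SB24011 on cGAMP, 802 for 10 uM, 709 for SB24011 against 7a and 18 for the interaction. These counts are lower by construction. With the other alternatives the counts of these first 5 comparisons stayed within 1.5 times, and that of the doses at 0. For 7a on cGAMP the replicate block gave 8 genes and DESeq2 38, and leaving out 1 library gave 0 to 48, the latter without replicate 3 of the 7a group.

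The interaction count of 54 was 33 with library size alone, 321 with the replicate block, 23 without library set 1, 173 with DESeq2 and 29 in the fit of the compared groups alone. Leaving out 1 library gave 23 (without cGAMP replicate 1) to 67 (without replicate 1 of the combined group). Without DMSO replicate 1 it gave 33, without DMSO replicate 3 29, without SB24011 replicate 3 31 and without replicate 2 of the combined group 33. Of the 54 genes 54 were also called with the block and with DESeq2, 28 with library size alone, 17 without set 1 and 25 with the compared groups alone. Otherwise the cause of the changes was not tested.

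The replicate block raised the counts of the first 5 comparisons to 6418, 7811, 7496, 7027 and 6683, in the order above. On average each of 18 libraries correlated best with its own set. Every same-set pair exceeded the minimum r of 0.1 for SB24011 alone against DMSO and for 7a on cGAMP. At least 1 pair lay below it in each of the other pairwise comparisons. In these the block also called Ifnb1 for SB24011 against 7a (adjusted p = 0.0334) and passed 5 of the 7 lists it added: NRF2 (0.0471) and macrophage identity (0.0261) for cGAMP, NRF2 for 20 uM SB24011 on cGAMP (0.00526), glycolysis for 10 uM (0.0321) and AhR targets for SB24011 against 7a (0.0388).

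Of 200 list tests 65 passed camera with its preset correlation and 12 with an estimated correlation. The number was 61 with RLE, 65 with library size alone, 72 with the block and 69 without set 1. RLE ended 4 calls and library size alone ended 4 and added 4. The block added 7, and leaving out set 1 ended 6 and added 10. No list reversed. Interferon-stimulated gene score differences kept their direction with RLE, library size alone and log2(FPKM + 1). Leaving out 1 library kept it in 6 of 6 fits for cGAMP, SB24011 alone and 7a. It was kept in 5 of 6 for 10 uM (-0.004 without its replicate 1), 4 of 6 for 20 uM (-0.007 without cGAMP replicate 2, -0.09 without replicate 1 of the combined group), 4 of 6 for SB24011 against 7a (0.081 without SB24011 replicate 3, 0.055 without 7a replicate 1) and 4 of 6 for the doses (0.063 without replicate 1 of the 10 uM group, 0.055 without replicate 3 of the 20 uM group), none of which passed a test.

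Of 287 calls of named genes 285 were kept with RLE, 284 with library size alone, 287 with the block, 284 with no filter on counts and 269 without set 1. DESeq2 kept 286 of 286 with a value, the fit of the compared groups 271 of 282, and limma on log2 FPKM 222 of 228. Leaving out 1 library kept 1750 of 1824, and none reversed in any alternative. In 75 cases an alternative gave no value for a gene. Of 45777 genes listed 22720 had a read in any library and 14650 had enough counts to test. Depth limits genes with few reads, such as Trim29 with 5 reads in 1 library and 0 in 17.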

Other observations

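The tests in this part were chosen after the values were seen.

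Circadian clock genes form a list written after Per2 and Cry2 were seen to change, with 17 of 19 members tested. Unless said otherwise the values leave out Per2, Cry2, Cry1 and Tef, which were called with 7a under another setting, but the list was still chosen for that result. Of the remaining 13, 9 rose and 2 fell with SB24011 alone (median log2 fold change 0.84, camera adjusted p = 0.00114, and 0.0162 with an estimated correlation). With 20 uM SB24011 on cGAMP 8 rose and 1 fell (median 0.71, 0.00157 and 0.0162), and with 10 uM 8 rose and 1 fell (median 0.67, 0.00114 and 0.0162). With cGAMP against DMSO 1 rose and 3 fell (0.538). With 7a on cGAMP no member was called by edgeR, and the list had a median of 0.27 (0.00417 and 0.024). Neither the doses (0.959) nor the interaction (0.287) passed. For 20 uM SB24011 against 7a, where leaving out the genes that moved with 7a would favour a difference, all 17 members had 6 higher and 1 lower (median 0.56, 0.00555), and the list did not pass with an estimated correlation (0.0845).

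Replicate 3 of 7a lay apart from replicates 1 and 2 in Per2, Cry1, Cry2 and Tef and, by less, in Nr1d2 (36.3, 34.7 and 29.7 CPM), but not in Nfil3 (17.8, 17.2 and 18.2 CPM) or Arntl (31.7, 27.6 and 32.9 CPM). Per2 stood at 4.67, 4.77 and 0.963 CPM in 7a replicates 1, 2 and 3, at 0.351, 1.23 and 0.474 CPM with cGAMP alone and at 5.32, 6.48 and 6.88 CPM with 20 uM SB24011. Cry1 stood at 53.1, 52.3 and 27.4 CPM with 7a, at 28.6, 28.4 and 28.7 CPM with cGAMP and at 57.9, 53.9 and 59.4 CPM with SB24011. Without 7a replicate 3, edgeR called Per2 (2.83, adjusted p = 0.00324), Cry1 (0.88, 1.88e-05), Cry2 (1.47, 0.00011), Tef (1.56, 0.000803) and Klf4 (1.31, 0.000324) among 48 genes.

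Genes grouped by the stem of their symbol gave 137 families and 1096 tests, of which 64 passed with the preset correlation and 0 with an estimated one. The splicing factor family Srsf fell in 10 of 10 members with SB24011 alone (median -0.39, adjusted p = 0.00191, 0.731 with an estimated correlation), in 10 of 10 with 20 uM on cGAMP (-0.34, 0.000817) and in 10 of 10 with 10 uM (-0.35, 0.000817). The 2 comparisons on cGAMP share the cGAMP libraries.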
